A study of Mus musculus with 9 samples.

How the data were processed

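The data are bulk RNA-seq of 9 mouse libraries that the labels describe as retina, in 3 groups of 3: young, aged and EGCG-treated aged. Per the labels' protocols, RNA was purified with a column kit of Qiagen (RNeasy mini plus) and libraries were prepared with a SMARTER mRNA-seq kit. Whether the kit kept strand, and whether the libraries of a group came from separate animals, is not given in the sources used here. The series design text says that the samples include duplicates, without saying what was duplicated.

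The authors deposited a table of raw counts per gene symbol and a table of FPKM values for the same 16231 genes, per the file headers. The submitters' processing notes name the builds GRCm38 and mm10, and the aligner, counter and gene annotation are not given in the sources used here. The deposited counts are whole numbers that sum to 34240500 to 39922044 per library, with 0 genes at 0 in every library and 0 repeated symbols, so genes without any count appear to have been left out. The deposited FPKM values equal the CPM of the same column total divided by a gene length that is the same in every library and whole to within 0.01 bp for 100% of genes, as checked here. Those lengths correlate with GENCODE M21 exon lengths across genes with a Spearman coefficient of 0.76. Of the symbols, 15712 matched a single GENCODE M21 gene on GRCm38 by name, and 16018 are protein-coding in RefSeq. Coordinates are those of GENCODE M21 on GRCm38.

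The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with its default minimum count of 10, quasi-likelihood fits (glmQLFit, glmQLFTest) of all 9 libraries with a coefficient per group, and Benjamini-Hochberg adjustment with a threshold of 0.05 over the 12747 genes that passed the filter. The 3 contrasts were aged against young, EGCG-treated aged against aged and EGCG-treated aged against young, and adjusted p-values of genes are from this test. TMM factors were 0.911 to 0.92 for the young libraries and 1.027 to 1.055 for the others. Gene lists, written before the data were examined, were tested two-sided with camera (limma 3.58.1) at a preset correlation between genes of 0.01, over lists with at least 5 tested members, with adjustment over the 33 lists so tested. Each was also tested with an estimated correlation, and the counts of changed members were repeated with p-values adjusted over the list alone. Where a call was kept, the adjusted p with an estimated correlation was still larger, and it is given only for some lists. Another 18 lists of liver functions and liver cell types were written after the most abundant transcripts had been seen, were adjusted among themselves and are named as added. Groups, tests, lists and the main alternatives were set before the data were examined. Camera compares a list with all other genes, and fry tests whether a list's genes move on balance in 1 direction without that comparison.

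Genes were named by a rule set before the data were examined: for each comparison up to 12 higher and 12 lower genes with the largest absolute log2 fold change among those that passed, with a mean of at least 5 CPM in a compared group and no overlap between the groups, an arrangement that chance gives for 10% of genes. Gene models without a name and immunoglobulin segments were not named. The rule adds up to 4 members of each list with the smallest p, the 10 opposite calls with the largest smaller change, and Cyfip1, Cyfip2, Akt genes and sex-linked genes. Some of the genes so named are not reported here. Genes given for their abundance or as photoreceptor genes were chosen after their levels had been seen, as was the retinal pigment epithelium gene Best1. A fold against a group at 0 counts is a lower bound against 3 counts over the group, and ratios with 1 to 3 counts in a group carry an exact 95% interval. These bounds, and the floors in CPM, cover counting error only, because the sources give no molecular identifiers. Reads of near-identical families (major urinary proteins, Saa1 and Saa2, Hspa1a and Hspa1b, Cyp2b, Cyp2c and Cyp3a genes, globins, MHC genes) could have been split or dropped by the authors' counting, so their values are uncertain, as are those of overlapping genes.

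The steps were tested on simulated data with the real library sizes and gene means, in which 200 of 12747 genes were changed. For aged against young, 98% of 4-fold, 72% of 2-fold, 76% of 1.5-fold and 40% of 1.2-fold changes were recovered, for EGCG-treated against aged 100%, 76%, 54% and 32%, and for EGCG-treated aged against young 90%, 66%, 70% and 42%. Among genes of at least 5 CPM, 2-fold and 4-fold changes were recovered in 100% of cases in all 3 comparisons. Unchanged genes were called in 0.12%, 0.03% and 0.06% of cases. In the real data far more genes were called (8857 of 12747 with age), so these rates may not carry over to it. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 3.79 to 4.79), so none was merged. The spread between libraries of a group was small, with a common biological coefficient of variation of 5.2 to 5.5% by group. For the genes that changed with age by more than 1, negative binomial counts were drawn with the treated group at the aged level and run through the same steps, a simulation added after the result had been seen.

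The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter or a filter of 10 CPM in 3 libraries, fits of the compared groups alone, the replicate number as a block, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with and without a filter at an FPKM of 1, a minimum log2 fold change of 1, an adjusted p under 0.1, removal of lens and red blood cell genes, and each library left out in turn. Chosen after the data had been seen were the removal of trends with gene length or GC content and a test against a fold of 1.5 (glmTreat). The libraries were also regrouped, and the effect of the shared aged libraries was assessed by 20 simulated data sets without effects. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.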

Results

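RNA was sequenced from 9 mouse libraries labelled as retinal tissue: 3 from young mice, 3 from aged mice and 3 from aged mice treated with EGCG (epigallocatechin gallate, the main catechin of green tea). The series title ties the study to damage of the retinal pigment epithelium and to Cyfip2 (cytoplasmic FMR1-interacting protein 2, a member of the actin-regulating WAVE complex) and AKT signalling. The ages, dose, duration and strain are not given in the sources used here. The libraries held 34240500 to 39922044 counts each over 16231 genes, of which 14029 to 14731 had a count in a given library. Unless said otherwise, gene levels are CPM, counts scaled to library size with TMM factors, given as mean ± SD of 3 libraries. Changes are log2 fold changes. The libraries of each group lay close together, with a common biological coefficient of variation of 5.4%, and principal components 1 and 2 of the log2 CPM, which held 52.6% and 29% of the variance, separated the 3 groups. No label says that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had counts in all 9 libraries, with Ddx3y at 89.6 CPM in the young, 56.6 in the aged and 39.4 in the EGCG-treated group. These genes did not move alike with age. Without each library in turn, Kdm5d ranged over 0.168 to 0.264 and Uty over -0.329 to -0.25, and both lost their call under some alternatives.

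The most abundant transcripts in these libraries labelled retina were those of plasma proteins, which hepatocytes are known to secrete. Alb, the gene of serum albumin, took 7.77 ± 0.041% (SD, n = 3) of all counts in the young, 8.62 ± 0.039% in the aged and 9.09 ± 0.1% in the EGCG-treated libraries. Apoe (apolipoprotein E) took 1.74 to 2.23% of counts by group mean, Trf (transferrin) 1.22 to 1.83% and Serpina3k 0.803 to 1.51%. The 24 genes of a list of liver plasma proteins, written after the most abundant transcripts had been seen, took 20.5 to 20.9% of counts in each library. Transcripts of photoreceptors were near the detection floor, which at 3 counts per library lay between 0.0751 and 0.0876 CPM of the library total. Sag (rod arrestin) had 15 counts over all 9 libraries together, Pde6b 1, Cnga1 1 and Best1, a gene of the retinal pigment epithelium, 4. Of the 65 members of 6 lists of retinal neurons that were in the table, 41 lay under 1 CPM in every library. Among the 24 others were the rod transducin gene Gnat1, at 4.09 to 29.2 CPM of the library total, and Reep6, at 609 to 943 CPM. The lists of cones, bipolar, amacrine, horizontal and retinal ganglion cells, and of lens, cornea and striated muscle, had 3 or 4 tested members each and were not tested as lists. No mitochondrially encoded gene was tested.

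**Figure D1:**
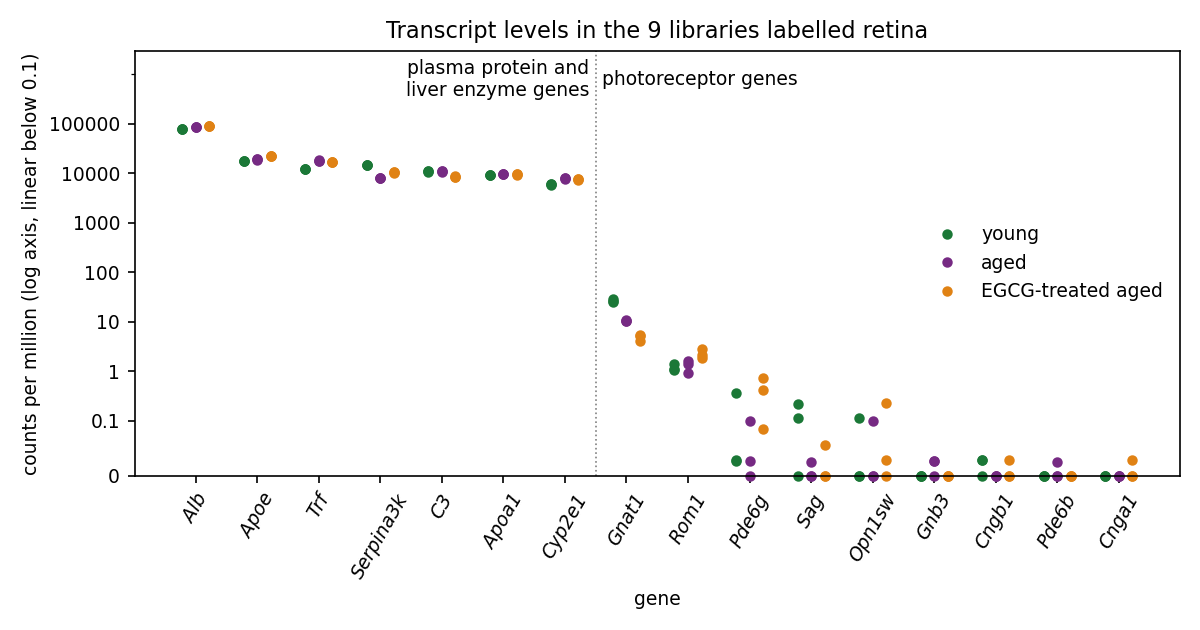
CPM of the library total for 7 plasma protein and liver enzyme genes and 9 photoreceptor genes (vertical axis logarithmic, linear below 0.1); each point is a library, coloured by group. Alb lay at 77300 to 92100 in every library, and Sag at no more than 0.223.

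Aged libraries were compared with young ones to see what differed with age without treatment. In the aged libraries immediate early genes and transcripts of macrophages and of the extracellular matrix were higher than in the young ones, and transcripts of acute phase proteins, of a drug-induced cytochrome P450 and of major urinary proteins were lower. Hspa1a and Hspa1b, near-identical genes of the inducible HSP70 chaperone whose reads could have been split between them, rose from 1.69 ± 0.55 to 117 ± 4.8 CPM (log2 fold change 6.11) and from 18.8 ± 0.59 to 602 ± 7.3 CPM (5.0). Cyp2b10, a cytochrome P450 known to be induced by foreign compounds, fell 302-fold, from 349 ± 7.8 to 1.16 ± 0.12 CPM (-8.24, SE 0.074, adjusted p = 2e-49). Saa1 and Saa2, genes of the acute phase protein serum amyloid A that also share reads, fell from 2020 ± 39 to 54.5 ± 0.63 CPM (-5.21) and from 2150 ± 45 to 31.8 ± 2.3 CPM (-6.08).

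Among genes with at least 5 CPM in a group and no overlap between the groups, the others with the largest increases included Ppp1r3g and Ppp1r3c, which target protein phosphatase 1 to glycogen (7.16 and 4.75). Depp1, a target of FOXO factors, rose from 3.07 to 270 CPM (6.45). The plasma cell gene Jchain (5.30), Arrdc3 (5.31), the immediate early receptor Nr4a1 (5.15) and Cd83 (4.64) rose, as did the matrix-associated genes Ccn1 (4.40) and Thbs1 (4.38). The largest decreases included those of the steroid hydroxylase gene Cyp21a1 (-5.20), Ttll8 (-5.92), Amigo3 (-4.42), Syt12 (-4.28), Mfsd2a, a transporter of lysophosphatidylcholine (-3.91), and Nrg4 (-3.66). Lcn2, the gene of the acute phase protein lipocalin 2, fell from 422 ± 14 to 33.6 CPM (-3.65). Mup17 and Mup15, members of the major urinary protein family whose reads could have been split among copies, fell as well (-4.16 and -3.87). Absence of overlap between the groups was a condition for naming these genes, so it is no added evidence for them.

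Among lists fixed before the data were examined, the immediate early genes rose: 22 of 23 measured members were higher and 0 lower, with a median change of 2.64 (camera adjusted p = 7.1e-28, but 0.000524 with an estimated correlation). Jun rose from 64 ± 2.8 to 556 ± 14 CPM, Fos from 1.75 ± 0.21 to 36 ± 1.2 CPM and Egr1 from 14.9 to 178 CPM. Of 26 genes of cholesterol synthesis and lipid supply, 24 rose and 1 fell (median 0.96, adjusted p = 7.1e-28, but 0.000524 with an estimated correlation). Insig1, a sterol-regulated retention protein, rose by 2.92, and Hmgcs1, an enzyme of the mevalonate pathway, by 2.21. Of 21 genes of microglia and macrophages, 20 rose and 0 fell (median 2.11, adjusted p = 1.4e-15). Among them were the lysozyme gene Lyz2 (from 25 ± 0.12 to 156 ± 2.7 CPM), the receptor gene Csf1r (from 11.3 to 85.6 CPM) and the complement gene C1qa (1.79). Antigen presentation rose as well, with 18 of 20 members higher and 1 lower (median 0.60, adjusted p = 3.3e-08), including Cd74 (2.6) and H2-Ab1 (2.52). Of 22 genes of cytokines and NF-kB targets, 20 rose and 1 fell (median 1.98, adjusted p = 0.0017). Il1b, the gene of interleukin 1 beta, rose from 1.82 ± 0.24 to 18.5 ± 1 CPM and Vcam1 rose by 1.84. All 13 tested lymphocyte genes rose (median 2.46, adjusted p = 0.034), a call that was lost at adjusted p = 0.108 with an estimated correlation. Complement genes were higher in 13 and lower in 5 of 19 (median 0.33, adjusted p = 0.0039, but adjusted p = 0.117 with an estimated correlation), and C3 fell by 0.20, a call that was lost in FPKM values.

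Connective tissue and vessel genes also rose with age. Of 27 genes of the extracellular matrix and basement membrane, 24 rose and 1 fell (median 1.59, adjusted p = 4.1e-07). Hspg2 rose by 2.29 and Col4a1 by 0.52, and Fn1, fibronectin, fell by 0.29. Of 15 fibroblast and sclera genes, 14 rose and 0 fell (median 1.86, adjusted p = 4.2e-07), with Dcn up by 1.72 and Col3a1 up by 2.19. Of 20 genes of endothelial cells and pericytes, 18 rose and 1 fell (median 0.83, adjusted p = 4.2e-05), including Kdr (1.84), Cdh5 (1.67) and Pecam1 (0.75). Angiogenesis genes rose in 15 and fell in 4 of 19 (median 1.03, adjusted p = 0.0058, but adjusted p = 0.0517 with an estimated correlation). Of 11 genes of outer segment phagocytosis 9 rose and 1 fell (median 0.68, adjusted p = 0.0064, but adjusted p = 0.0643 with an estimated correlation), led by the receptor tyrosine kinase Axl (2.59). Photoreceptor transcripts were near the detection floor, so the names of retinal lists do not show that those cells were present in these libraries.

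Lists that fell with age included those of the respiratory chain and of reactive gliosis. All 38 nuclear genes of the respiratory chain fell, by little (median -0.45, or -0.25 in FPKM values; adjusted p = 3e-09, but adjusted p = 0.13 with an estimated correlation). Cycs, cytochrome c, fell by 1.02 and Ndufa8 by 0.85. Of 13 genes of reactive gliosis, 9 fell and 4 rose (median -0.80, adjusted p = 3.6e-13). The members that fell include Serpina3n (from 3180 ± 45 to 568 ± 7 CPM), Steap4 (-2.62), Stat3 (-0.80) and Bcl3 (-2.12), which are also known as inflammation-induced genes outside glia. Of 25 acute phase proteins, a list added after the most abundant transcripts had been seen, 24 fell and 1 rose (median -1.11, adjusted p = 3.8e-92, but 0.000195 with an estimated correlation). The fibrinogen genes Fga, Fgb and Fgg were among them (-1.06, -1.15 and -1.08), and 2 genes of the list are also in the gliosis list. All 14 tested major urinary protein genes, a list added in the same way, fell (median -1.20, adjusted p = 1.4e-10).

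Other lists had members that moved in both directions. Targets of NRF2 and antioxidant enzymes rose in 9 and fell in 16 of 27 (median -0.18, which became 0.02 in FPKM values). Their camera test was downward (adjusted p = 0.0064, but adjusted p = 0.0679 with an estimated correlation). Gclc, which limits glutathione synthesis, rose by 1.35, and Sod2 fell by 0.74. Of 30 p53 targets and genes of cell death and senescence, 18 rose and 7 fell (median 0.52, adjusted p = 0.025, but adjusted p = 0.117 with an estimated correlation), with Bbc3 up by 3.80 and Gadd45a down by 2.31. Of 19 circadian clock genes, 9 rose and 7 fell. The mean (0.34) and the test were upward (adjusted p = 0.01, but adjusted p = 0.0643 with an estimated correlation), while the median (-0.03) turned to 0.08 with upper-quartile factors and 0.15 in FPKM values. Of 30 genes of heat shock and the unfolded protein response, 13 rose and 16 fell (17 adjusted over the list alone), with a median of -0.10 against a mean of 0.49 and an upward test that did not pass (adjusted p = 0.059). Hspb1 rose by 3.14 and Xbp1 fell by 1.56. Of 9 neutrophil genes 4 rose and 1 fell, with a median of 0.25, a mean of 1.59 and a downward test that did not pass (adjusted p = 0.2). The list of the retinal pigment epithelium had 6 higher and 7 lower members of 15 (7 and 7 adjusted over the list alone; median -0.10, mean 0.83, adjusted p = 0.6).

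By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8857 of the 12747 genes tested differed between aged and young libraries, 4261 higher and 4596 lower. The higher share of 48.1% became 57.9% with upper-quartile factors and 62.1 to 67.8% in FPKM values. The median over all genes moved by up to 0.123 (FPKM with a pseudocount of 0.1). Some lists moved further in FPKM values: the median of drug-metabolising enzymes went from -0.20 to 0.03 and that of urea cycle genes from -0.37 to -0.17. Changes with age of 0.20 or less therefore depend on the scaling. On log2(FPKM + 1), which understates changes of low genes, the medians were 1.17 for fibroblasts, 1.42 for lymphocytes, 1.17 for cytokines, 0.32 for p53 targets and 0.66 for angiogenesis. Of the 33 lists tested by camera, 17 were called and 9 of these remained called with an estimated correlation. Another grouping of the same libraries called 15. Counts adjusted over the list alone were the same for 28 of the 33 lists in this comparison, 27 in the comparison of treated with untreated aged libraries and 26 in that of treated with young ones, and are given where they differ for a list described.

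**Figure D2:**
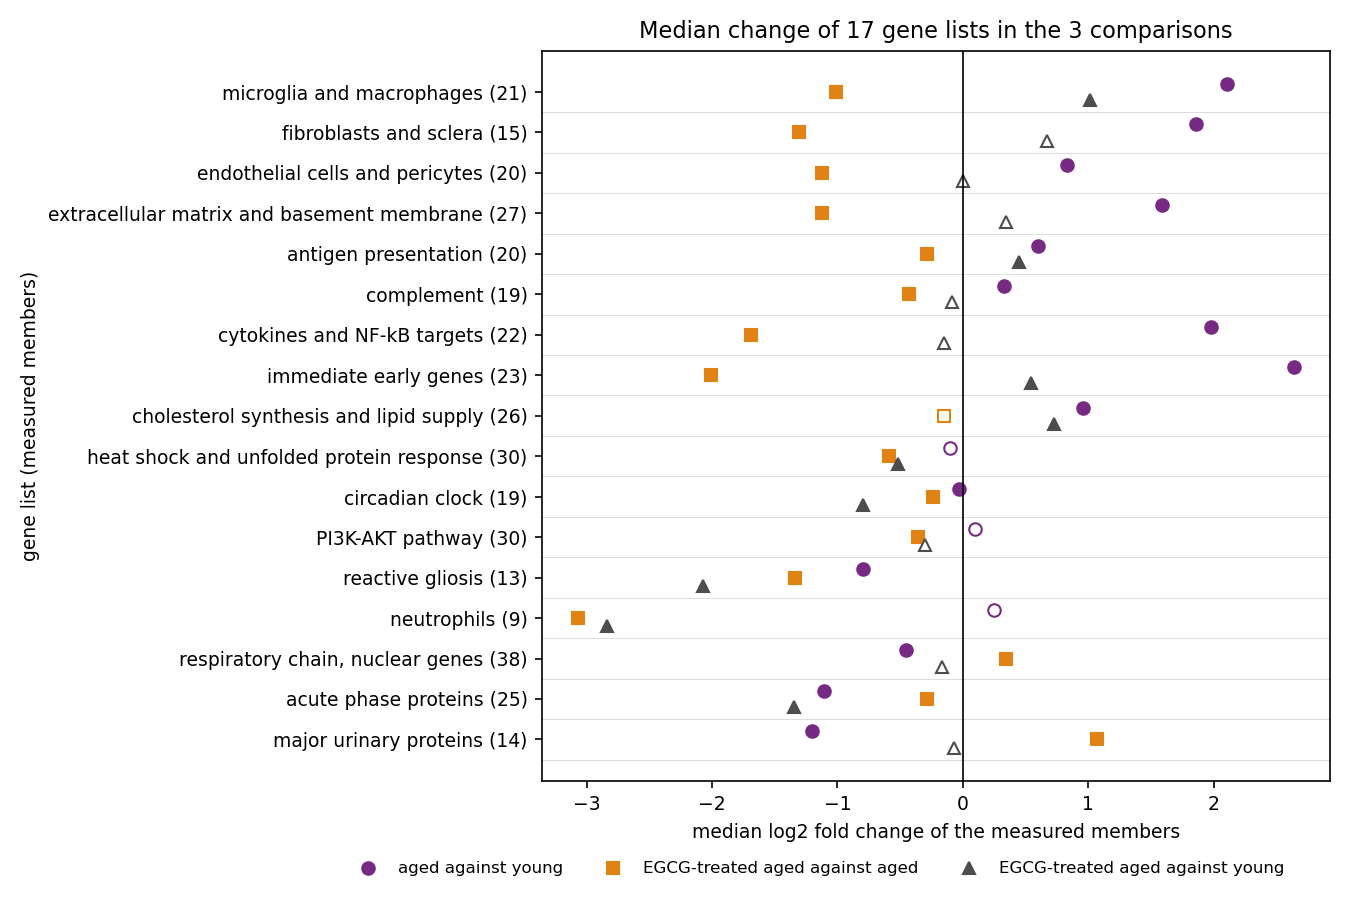
Median log2 fold change of 17 gene lists (vertical axis, with the number of measured members) in aged against young (circles), EGCG-treated aged against aged (squares) and EGCG-treated aged against young (triangles); filled marks have a camera adjusted p under 0.05, and the acute phase and major urinary protein lists were added after the most abundant transcripts had been seen. Immediate early genes lay at 2.64, -2.01 and 0.54, and the circadian clock median with age, -0.03, turned to 0.08 with upper-quartile factors.

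EGCG-treated aged libraries were compared with untreated aged ones to see what differed with the treatment. Stress-induced genes, metallothioneins, output genes of the circadian clock and markers of macrophages, endothelium and matrix were lower in the treated libraries, and major urinary proteins and members of the Cyp2c family were higher. Hspa1a and Hspa1b fell to 1.64 ± 0.11 and 21.1 ± 2.8 CPM (-6.15 and -4.83). Mt1 and Mt2, genes of metal-binding metallothioneins, fell from 163 ± 4.1 to 4.25 ± 0.72 CPM (-5.26) and from 99.5 ± 5.4 to 2.47 ± 0.41 CPM (-5.33). Mup17 rose from 17 ± 2.5 to 296 ± 64 CPM (4.12, SE 0.1, adjusted p = 2.4e-32) and Cyp2c69 from 0.868 ± 0.13 to 15.2 ± 0.93 CPM (4.12, SE 0.18, adjusted p = 1.2e-23).

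The further genes with the largest decreases were Ppp1r3g (-6.45) and the regulators of G protein signalling Rgs4 and Rgs16 (-4.72 and -4.34). The clock genes Bhlhe41 (-4.39) and Dbp (-4.29, from 51.5 ± 1.4 to 2.62 ± 0.44 CPM) and the stress genes Atf3 (-4.25, from 37.2 to 1.95 CPM) and Gadd45b (-4.15) completed this group. The further genes with the largest increases included Cyp2c40 (3.85, from 2.3 to 33.4 CPM), Mup15 and Mup18 (3.52 and 2.81). Npas2, a paralog of CLOCK that pairs with BMAL1, rose from 1.27 to 12.5 CPM (3.29), and Nr0b2, which encodes the bile acid-induced repressor SHP, from 13.7 to 92.7 CPM (2.76). The others were the lipid droplet gene Pnpla3 (2.77), Zbtb7c (2.70), Tsku (2.64), Chrna4 (2.53) and Fam110a (2.46). Reads of the Mup and Cyp2c genes could have been split between copies, and Mup18 varied widely among the treated libraries (68.4 ± 42 CPM).

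Of 30 genes of heat shock and the unfolded protein response, 19 fell and 9 rose (median -0.59, camera adjusted p = 4.1e-21, but 0.00111 with an estimated correlation). Hspb1 (-2.44), Hsph1 (from 193 to 40.9 CPM), Hspa8 (-1.09) and Herpud1 (-1.89) fell, and Xbp1 rose by 0.53. Circadian clock genes fell in 12 and rose in 4 of 19 (median -0.24, or -0.04 with the length trend removed; mean -1.07, adjusted p = 6.5e-16). Per1 fell from 61.7 ± 2.1 to 3.82 ± 1.1 CPM, Bhlhe40 from 977 to 78.2 CPM, Nr1d1 from 393 to 103 CPM and Tef by 1.55. Arntl, which encodes the activator BMAL1, rose from 9.11 ± 0.077 to 33.7 ± 1.2 CPM. Of 23 immediate early genes, 18 fell and 5 rose (median -2.01, adjusted p = 2.3e-08). Jun fell by 2.08 and Maff by 3.84, and Fos rose by 1.04 and Ier2 by 1.69. Cytokines and NF-kB targets fell in 19 and rose in 0 of 22 (median -1.69, adjusted p = 2.2e-06), with Il1b at 2.01 ± 0.44 CPM in the treated libraries and Tnfaip3 down by 2.70. Of 13 genes of reactive gliosis, 11 fell and 0 rose (median -1.34, adjusted p = 5.4e-12). Of 25 acute phase proteins 19 fell and 4 rose (median -0.29, or -0.53 with the length trend removed). Their camera adjusted p was 2e-19, but 0.00443 with an estimated correlation.

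**Figure D3:**
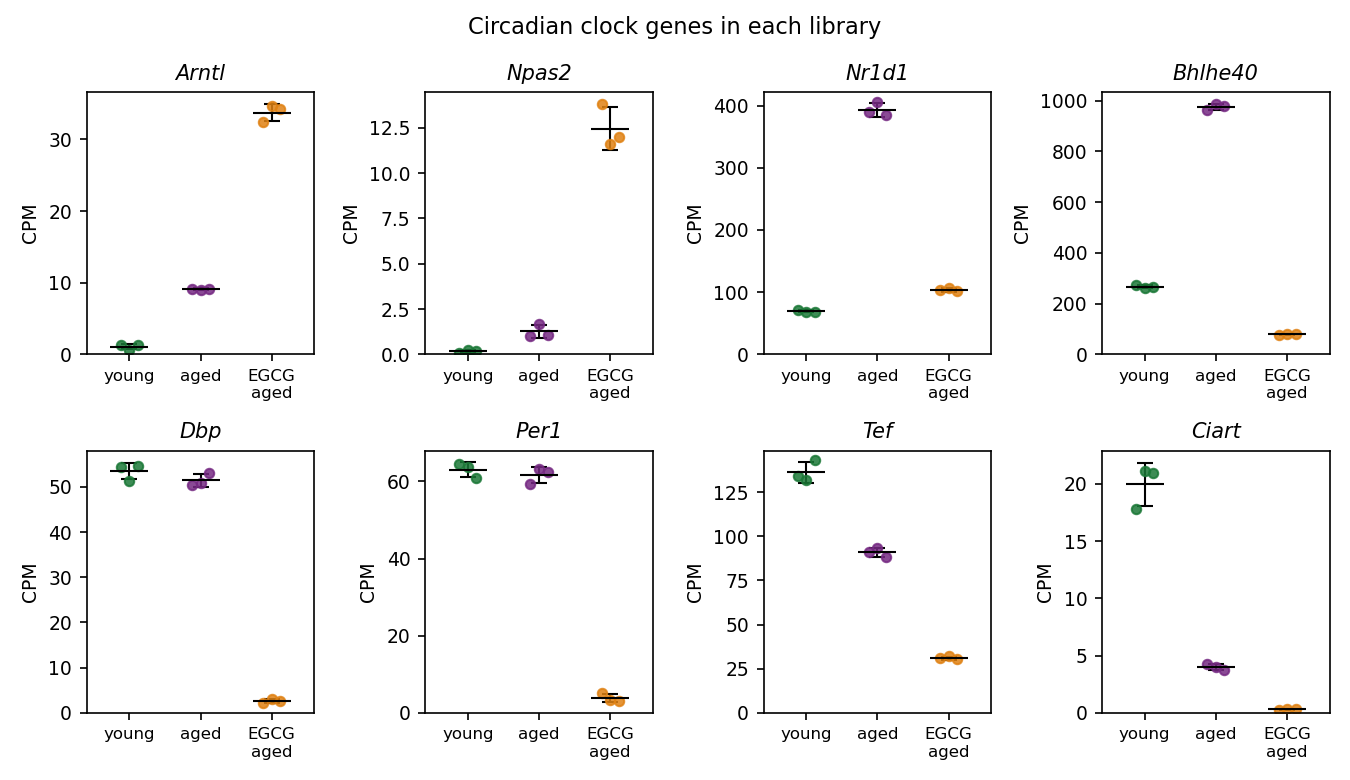
CPM with TMM factors of 8 circadian clock genes; each point is a library, the long bar is the mean and the whiskers are the SD of 3 libraries. Dbp and Per1 lay near 53.5 and 63 CPM in the young and 51.5 and 61.7 CPM in the aged group but at 2.62 and 3.82 CPM in the EGCG-treated group. The other genes shown also differed with age. Arntl, Npas2, Nr1d1 and Bhlhe40 were higher in aged than in young libraries, and Tef and Ciart were lower.

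Markers of macrophages, neutrophils, vessels and connective tissue were lower in the treated than in the untreated aged libraries. Those of lymphocytes were not called (2 higher and 1 lower of 13, or 0 and 1 adjusted over the list alone; camera adjusted p = 1). Their median of 0.31 was 0.11 with the length trend removed and turned to -0.29 in FPKM values. Of 21 genes of microglia and macrophages, 16 fell and 0 rose (median -1.01, adjusted p = 1.6e-08), including Csf1r (-1.91), Lyz2 (-1.55), Mrc1 (-1.98) and C1qa (-0.80). All 9 neutrophil genes fell (median -3.07, also with genes near 0 counts at their bound; adjusted p = 7.9e-05), among them S100a9 (from 6.67 to 0.793 CPM). Endothelial and pericyte genes fell in 16 and rose in 1 of 20 (median -1.12, adjusted p = 3.7e-06), with Kdr among the lower ones (-1.90). Matrix and basement membrane genes fell in 22 and rose in 1 of 27 (median -1.12, adjusted p = 1.8e-08), including Hspg2 (-1.93) and Col4a1 (-1.56). Fibroblast and sclera genes fell in 13 and rose in 0 of 15 (median -1.31, adjusted p = 1.8e-05). Angiogenesis genes fell in 13 and rose in 2 of 19 (median -0.57, adjusted p = 0.0002). Antigen presentation genes fell in 13 and rose in 3 of 20 (median -0.29, or -0.46 with the length trend removed; adjusted p = 5.2e-05), and complement genes fell in 16 and rose in 0 of 19 (median -0.43, adjusted p = 2.6e-05). Red blood cell genes rose in 6 and fell in 0 of 7 (median 0.70, or 0.32 with the length trend removed; adjusted p = 0.0032), with the globin gene Hba-a1 at 40 CPM in the untreated and 73.3 CPM in the treated aged libraries.

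Among pathways, 19 of 29 genes of autophagy and the lysosome fell and 3 rose (median -0.22, adjusted p = 0.00024). Ulk1, a kinase that starts autophagy, fell from 143 to 49.7 CPM, and Gabarapl1 fell by 0.96. Nuclear genes of the respiratory chain rose in 31 and fell in 2 of 38 (3 lower adjusted over the list alone; median 0.34, but 0.02 with the length trend removed; adjusted p = 3.2e-06, but adjusted p = 0.226 with an estimated correlation). Cycs rose by 0.65 and Atp5b fell by 0.14. Cytosolic ribosomal protein genes rose in 62 and fell in 3 of 79 (63 higher adjusted over the list alone; adjusted p = 1.8e-05, but adjusted p = 0.452 with an estimated correlation). Their median of 0.20 turned to -0.14 once the trend of fold change with gene length was removed. All 12 of the 14 tested major urinary protein genes that changed rose (median 1.07, adjusted p = 4.8e-15), and Mup3 rose from 3520 to 6260 CPM. Genes of cholesterol synthesis did not pass as a list (9 higher and 12 lower of 26, median -0.15, adjusted p = 0.14). NRF2 targets had 15 higher and 7 lower of 27, with a median of 0.20 (0.01 with the length trend removed). Their mean was -0.32, and the test was downward and did not pass (adjusted p = 0.31). Hmox1 fell by 1.93 and Gclc rose by 0.49.

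By the same edgeR test 8064 of 12747 genes differed, 4053 higher and 4011 lower. The higher share of 50.3% became 56.9% with upper-quartile factors, which moved the median over all genes by 0.059, and 47.2 to 52% in FPKM values. On log2(FPKM + 1) the medians were -0.86 for fibroblasts, -1.73 for neutrophils and -0.98 for immediate early genes. Camera called 18 of the 33 lists, of which 16 remained called with an estimated correlation. Another grouping of the same libraries also called 18, so the number of called lists does not set the real grouping apart. That grouping mixes the groups unevenly and keeps part of their difference, so it does not show how many lists chance alone would call. Fold changes followed gene length (Spearman correlation across genes -0.3, with a median of 0.22 in the shortest and -0.24 in the longest 25% of genes), and with that trend removed, an alternative chosen after the data had been seen, 6370 of the 8064 calls were kept in direction and 135 were reversed.

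Cyfip2, the gene named in the series title, was higher in the aged libraries than in either other group. It rose from 1 ± 0.067 CPM (97 counts over the 3 young libraries) to 3.41 ± 0.32 CPM with age (412 counts), a log2 fold change of 1.76 (SE 0.26, adjusted p = 1.3e-07). It fell to 1.13 ± 0.06 CPM (124 counts) with EGCG (-1.59, SE 0.25, adjusted p = 7.5e-07). Treated aged and young libraries differed by 0.17 (SE 0.28, adjusted p = 0.62). On the log2(FPKM + 1) scale without a filter, which understates changes of low genes, the differences with age and with EGCG were 0.197 and -0.177 and also passed. Akt1 and Akt2, which were more abundant, fell with age, from 76.7 ± 4.3 to 48 ± 1.3 CPM (-0.68) and from 114 ± 4.7 to 94.1 ± 2.5 CPM (-0.28), although the call of Akt2 was lost in FPKM values (-0.077 with a pseudocount of 1). With EGCG, Akt1 fell further by 0.14 (adjusted p = 0.011) and Akt2 by 0.12 (adjusted p = 0.007), calls that were lost with upper-quartile factors (-0.084 and -0.061). The change of Akt2 turned to 0.008 with the trend with gene length removed. Cyfip1, the abundant paralog, was at 49.4 ± 4.7 CPM in young and 50.4 ± 0.29 CPM in aged libraries (0.03, adjusted p = 0.63) and fell by 0.37 with EGCG (adjusted p = 1.2e-07). Its difference with age depended on the scaling and was called higher with upper-quartile factors (0.137) and in FPKM values (0.208 with a pseudocount of 1). Markers of macrophages and endothelium rose with age and fell with EGCG in the same libraries (Csf1r by 2.92 and -1.91, Kdr by 1.84 and -1.90). Because the title names Cyfip2, it may have been chosen on these samples, and its change is then not independent evidence.

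On GRCm38, with GENCODE M21 coordinates, Cyfip2 is a protein-coding gene on the minus strand of chromosome 11 from 46193850 to 46312859, and its span holds Fndc9 on the opposite strand (46235531 to 46239872) and the processed pseudogene Gm12568 on the same strand. Whether counting used strand is not given in the sources used here, so reads from overlapping genes could not be told apart. Cyfip2 had 97 to 412 counts per group, and the SEs of its fold changes were 0.25 to 0.28.

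**Figure D4:**
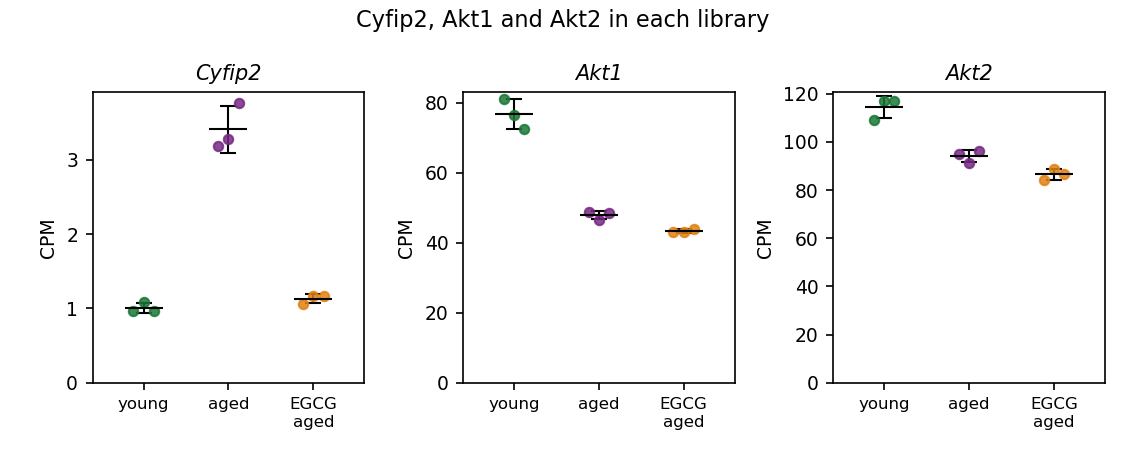
CPM with TMM factors of Cyfip2, Akt1 and Akt2; each point is a library, the long bar is the mean and the whiskers are the SD of 3 libraries. Cyfip2 averaged 1, 3.41 and 1.13 CPM in the young, aged and EGCG-treated groups, and Akt1 76.7, 48 and 43.4 CPM.

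The PI3K-AKT pathway as a list did not pass with age, with 13 higher and 9 lower of 30 (median 0.10, camera adjusted p = 0.16), and fell with EGCG, with 22 lower and 3 higher (median -0.36, or -0.23 with the length trend removed; adjusted p = 7.3e-05). The insulin receptor substrate gene Irs2 rose from 52.5 ± 4 to 156 ± 5.3 CPM with age and fell to 33.9 ± 1.1 CPM with EGCG, and Foxo3 went from 37.2 to 101 to 44.8 CPM. Irs1 rose with age by 2.43 and again with EGCG by 0.58, and Mtor fell by 0.36 and by 0.59. The WAVE regulatory complex and its partners passed in neither comparison: 7 of 17 members were higher and 5 lower with age (median 0.03, adjusted p = 0.6), and 3 were higher and 7 lower with EGCG (median -0.15, adjusted p = 0.45). Nckap1l, the haematopoietic member of the complex, rose by 2.92 and fell by 1.44, and Nckap1, its widely expressed paralog, fell by 0.20 and by 0.15, the former lost in FPKM values (-0.004).

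EGCG-treated aged libraries were compared with young ones to see what still separated them. Metallothioneins and acute phase proteins were lower in the treated aged libraries, genes of cholesterol synthesis and several immediate early genes were higher, and clock genes differed in both directions. Mt2 fell 406-fold, from 1010 ± 36 to 2.47 ± 0.41 CPM (-8.66, SE 0.054, adjusted p = 1.1e-55), and Mt1 311-fold, from 1320 ± 45 to 4.25 ± 0.72 CPM (-8.28). Saa2 and Saa1 (-7.21 and -6.06) and Cyp2b10 (-6.96) fell as well. Cyp2b9 (6.33), Npas2 (6.12), Depp1 (5.61) and the cell death gene Bbc3 (5.47, from 0.432 to 19.4 CPM) rose, as did Fos (5.40, from 1.75 to 73.8 CPM), Arntl (4.99, from 1.06 ± 0.35 to 33.7 ± 1.2 CPM) and Egr1 (4.34).

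Further increases were those of Ppp1r3c (3.64), Fam89a (3.64), Pnpla3 (3.56) and Chka, the choline kinase gene (3.56). Further decreases were those of the clock repressor Ciart (-6.08), the niacin receptor Hcar2 (-5.83), Lcn2 (-5.33), Arid5a (-5.25), Syt12 (-5.19), Cyp21a1 (-5.00) and Usp2 (-4.67). Genes that had risen or fallen with age and were not called between treated aged and young libraries included Hspa1a (-0.04, adjusted p = 0.86), Mup17 (-0.04, adjusted p = 0.71, but called at -0.219 with the length trend removed), Thbs1 (0.29, adjusted p = 0.24, but called at 0.56 without young replicate 3), Il1b (0.14, adjusted p = 0.5) and the endothelial gene Kdr (-0.05, adjusted p = 0.58). The signs of Hspa1a, Mup17 and Kdr turned under other scalings.

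Of 26 genes of cholesterol synthesis and lipid supply, 21 rose and 3 fell (22 higher adjusted over the list alone), with a median of 0.73. Their camera adjusted p was 1.3e-20, but 0.00139 with an estimated correlation. Insig1 rose by 2.72, Hmgcs1 by 2.02 and Srebf1, a master regulator of lipid synthesis, by 1.65. Immediate early genes rose in 11 and fell in 3 of 23 (median 0.54, adjusted p = 4.1e-09). Microglia and macrophage genes rose in 16 and fell in 0 of 21 (median 1.01, adjusted p = 0.0012), with Lyz2 at 53.1 against 25 CPM. Of 13 genes of reactive gliosis, 10 fell and 1 rose (median -2.07, adjusted p = 1.3e-31, but 0.000847 with an estimated correlation). Of 30 genes of heat shock and the unfolded protein response, 22 fell and 6 rose (median -0.52, or -0.33 in FPKM values; adjusted p = 3.8e-07). Of 19 clock genes, 11 fell and 6 rose (median -0.80, adjusted p = 0.00028), and of 9 neutrophil genes, 7 fell and 0 rose (median -2.84, or -2.95 with genes near 0 counts at their bound and -1.26 in FPKM values; adjusted p = 0.00013). Acute phase proteins fell in 24 and rose in 1 of 25 (median -1.35, adjusted p = 1.2e-137, but 0.000108 with an estimated correlation). Major urinary proteins did not pass (4 higher and 6 lower of 14, median -0.07, adjusted p = 0.89).

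A further 7 lists were called by camera and lost their call with an estimated correlation. Lymphocyte genes were higher in 12 of 13 (adjusted p = 0.047, but adjusted p = 0.156 with an estimated correlation) and red blood cell genes in 4 and lower in 1 of 7 (0.047 and 0.156 in the same order). Visual cycle genes were higher in 6 and lower in 1 of 10 (7 higher adjusted over the list alone; adjusted p = 0.011, but adjusted p = 0.156 with an estimated correlation). Antigen presentation genes were higher in 14 and lower in 3 of 20 (adjusted p = 0.033, but adjusted p = 0.184 with an estimated correlation). NRF2 targets were higher in 14 and lower in 9 of 27 (15 higher adjusted over the list alone). Their median was 0.10 (0.26 with upper-quartile factors and in FPKM values, 0.03 with the length trend removed), their mean -0.47 and the test downward (adjusted p = 0.026, but adjusted p = 0.184 with an estimated correlation). Ribosomal protein genes were higher in 47 and lower in 7 of 79 (adjusted p = 0.041, but adjusted p = 0.793 with an estimated correlation), with a median of 0.13 that was 0.29 with upper-quartile factors and turned to -0.04 with the length trend removed. Autophagy genes were higher in 4 and lower in 15 of 29 (adjusted p = 0.028, but adjusted p = 0.156 with an estimated correlation), with a median of -0.09 that turned to 0.08 with upper-quartile factors and 0.09 in FPKM values. Not called were cytokines and NF-kB targets (3 higher and 6 lower of 22, median -0.15, adjusted p = 0.78) and matrix genes (11 higher and 5 lower of 27, median 0.34, adjusted p = 0.72). Lists of fibroblasts (9 higher and 0 lower of 15, median 0.67, or 0.25 in FPKM values; adjusted p = 0.15) and endothelium (5 higher and 6 lower of 20, or 4 and 6 adjusted over the list alone; adjusted p = 0.78) were not called either.

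The edgeR test called 8014 of 12747 genes, 3927 higher and 4087 lower. The higher share of 49% became 65.6% with upper-quartile factors and 64.3 to 66.9% in FPKM values, and these scalings moved the median over all genes by up to 0.165, so smaller changes depend on the scaling. Somewhat larger ones can depend on it too, since the median of PPAR-alpha targets went from -0.36 to -0.14 in FPKM values.

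Genes that changed with age and in the opposite direction with EGCG were counted to see how far the treated libraries went back towards the young ones. There were 4678 such genes, 2313 higher with age and then lower, and 2365 lower with age and then higher. Independent lists of the same sizes would share 1341 and 1461 genes. A further 1546 genes changed in the same direction in both comparisons, where independent lists would share 2801. Ppp1r3g, Hspa1a and Hspa1b were among the 10 opposite calls with the largest changes. Other members were low in at least 1 group. The neutrophil granule genes Mpo and Ltf and the nitric oxide synthase gene Nos2 had 1 count over the 3 young libraries, and in aged libraries they were 115-fold (95% counting interval 20.3 to 4560), 171-fold (30.3 to 6780) and 149-fold (26.4 to 5920) higher. Ltf had 0 counts over the treated libraries and was at least 64.6-fold lower there than in aged ones, against a floor of 3 counts over the group. Mpo and Nos2 had 1 count each there, with aged libraries 130-fold (23 to 5170) and 169-fold (30 to 6720) higher. Ngp, another neutrophil granule gene, had 396 counts in aged and 1 in treated libraries, a ratio of 360 (64.3 to 14300). Slc15a2, a peptide transporter gene, went the other way, with 1 count in aged libraries, a young level 319-fold (56.8 to 12700) and a treated level 224-fold (39.8 to 8900) higher. Zfp941, with 0 counts in aged libraries, was at least 7.07-fold higher in young and at least 28.6-fold higher in treated ones, but its call with age was lost on log2(FPKM + 1) without a filter (-0.057). Intervals and floors cover counting error only.

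Both comparisons use the same aged libraries, which alone pulls their fold changes apart. The correlation of the fold changes across genes was -0.517, and simulated unchanged groups that share the aged libraries gave -0.48 on average (-0.51 to -0.46 over 20 simulations) with a mean of 0.25 opposite calls. The covariance was -0.419 against a simulated -0.022, a difference of -0.397. With 3 aged libraries the aged group could not be split into parts of at least 2 libraries, so part of the excess may come from the shared libraries, and genes are not independent replicates. Of the 2633 genes that changed with age by more than 1 on the log2 scale, 81.5% moved towards the young level with EGCG, 1190 lay closer to the young than to the aged level, and the median share of the age change undone was 44.7%. Simulations with the treated group drawn at the aged level keep the selection rule and the shared libraries. They selected 2801.8 genes on average (2760 to 2839 over 20 simulations) and gave 54.6% (52.7 to 56.9), 43 genes (30 to 61) and 1% (0.5 to 1.4). The simulations hold only the spread between libraries. They cannot tell a return with treatment from another difference that the aged libraries alone carry.

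**Figure D5:**
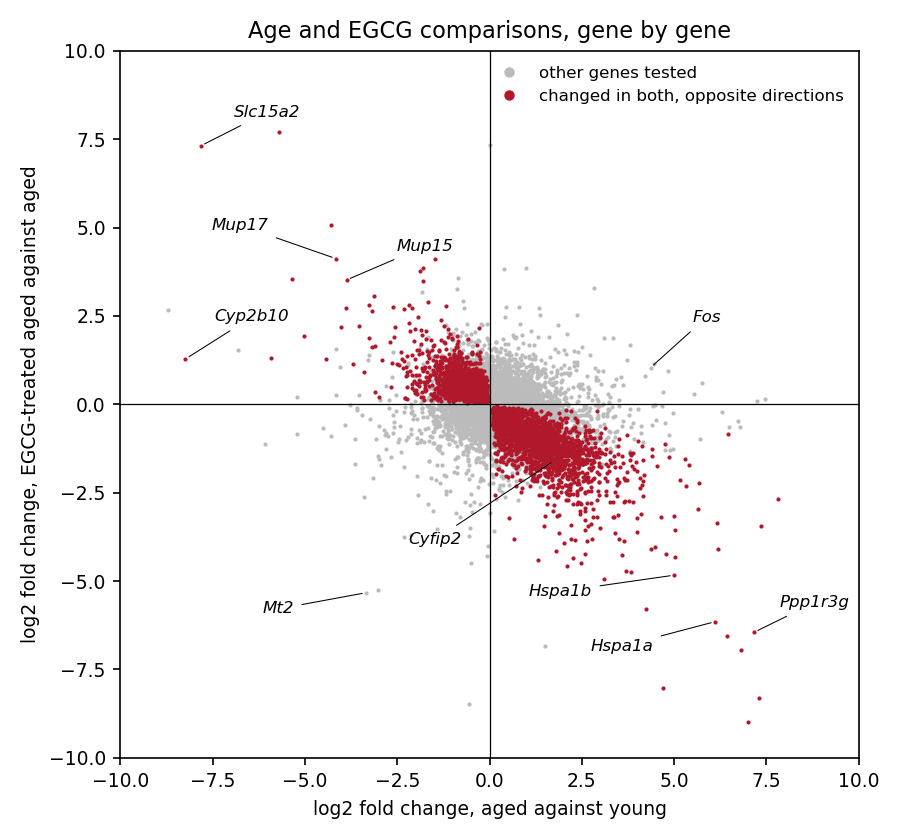
Fitted log2 fold changes of the 12747 tested genes in aged against young (horizontal axis) and in EGCG-treated aged against aged libraries (vertical axis); each point is a gene, and red points passed the test in both comparisons in opposite directions. Hspa1a lies at 6.11 and -6.15 and Fos at 4.36 and 1.04; fitted values of genes near 0 counts, such as Slc15a2, depend on the prior count.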

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

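Removal of the trends with gene length and GC content and the test against a 1.5-fold change were chosen after the results had been seen, and the other alternatives before. The counts of changed genes stayed within 1.5 times the reported ones under DESeq2 (8786, 7854 and 7940 for aged against young, EGCG-treated aged against aged and EGCG-treated aged against young), limma-voom (8866, 8222 and 7884) and upper-quartile factors (8737, 8166 and 8369). With a filter of 10 CPM, which leaves fewer genes, 5897 differed with age. A minimum log2 change of 1 left 2633 (1950 higher), 1675 (452 higher) and 1963 (1221 higher) genes and 973 opposite calls, 840 of them higher with age, and glmTreat against a 1.5-fold change left 3145 (2017 higher), 1794 (533 higher) and 2432 (1264 higher), because both ask for larger changes. The correlation between the age and EGCG fold changes was -0.507 without a filter, -0.405 at 10 CPM, -0.548 in fits of the compared groups alone, -0.423 on log2(FPKM + 1), -0.457 on log2(FPKM + 0.1), -0.436 on log2(FPKM + 1) without a filter and -0.509 with the length trend removed. The cause was not tested.

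Of the lists, 9 were called with age and 7 between treated aged and young libraries with an estimated correlation, and 8 in the latter at 10 CPM. fry, which does not compare a list with other genes, called 29, 30 and 29. Cyfip2 kept its direction and call under every alternative that gave a value for both comparisons with the aged group, and gave none with the filter of 10 CPM or with a filter on FPKM. Without each library in turn, the gene counts ranged over 8396 to 8944, 7457 to 8177 and 7606 to 8014, the opposite calls over 4235 to 4564, the correlation over -0.527 to -0.507, Cyfip2 over 1.681 to 1.815 with age and -1.637 to -1.509 with EGCG, and the lists over 17 to 18, 18 to 18 and 12 to 14.

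Replicate numbers did not pair the libraries: 0 of 9 same-numbered pairs had a correlation of deviations above 0.1 (-0.04 to 0.02) and 0 libraries matched their own number best. With the replicate block, 8749, 7957 and 7907 genes and 4593 opposite calls were found, with a correlation of -0.519.

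The 143 named genes gave 220 results, of which 204 kept direction and call under every alternative, 10 lost their call and 4 gained one under at least 1 alternative, and 6 reversed, with some counted under more than 1 of these. The reversed ones were small and none passed after reversal, and the cause was not tested. With the length trend removed, Cyfip1 was at -0.039 with age, Akt2 at 0.008 and Uty at 0.105 with EGCG, and Kdr at 0.025 between treated aged and young libraries. For that last comparison, upper-quartile factors gave 0.127 for Hspa1a, 0.11 for Kdr and 0.128 for Mup17, the filter of 10 CPM 0.048, 0.031 and 0.048, log2(FPKM + 1) 0.058, 0.072 and 0.128 with or without a filter, and log2(FPKM + 0.1) 0.155, 0.112 and 0.129. limma-voom gave 0.005 for Hspa1a, and removal of the GC trend 0.055 for Mup17. Without each library in turn, Cyfip1 with age ranged over -0.021 to 0.106, and between treated aged and young libraries Hspa1a over -0.184 to 0.261 and Mup17 over -0.139 to 0.132.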

Other observations

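The liver lists, the regroupings of the libraries and the tests of explanations in this part were all chosen after the result was seen. Several lists of hepatocyte genes, not described so far, were lower in aged than in young libraries. Of 30 targets of PPAR-alpha and genes of fatty acid oxidation, 25 fell and 5 rose (median -0.45, or -0.25 in FPKM values; camera adjusted p = 1.5e-08), among them Cyp4a14, a fatty acid hydroxylase, from 187 ± 5.4 to 56.2 ± 2.1 CPM, and Cpt1a (-0.68). Of 25 genes of the urea cycle and amino acid breakdown, 22 fell and 3 rose (median -0.37, or -0.17 in FPKM values; adjusted p = 1.4e-11), including Tat (from 3730 to 1680 CPM) and Asl (from 993 to 447 CPM). Genes that are higher in male liver fell in 11 and rose in 4 of 15 (median -0.70, adjusted p = 2.3e-08), with Selenbp2 down from 933 ± 25 to 150 ± 4.2 CPM, and periportal hepatocyte genes fell in 15 and rose in 4 of 20 (median -0.28, or -0.08 in FPKM values; adjusted p = 2.6e-06). Of 30 drug-metabolising enzymes 16 fell and 11 rose (adjusted p = 1.7e-05), with a median of -0.20 that turned to 0.03 in FPKM values. Cyp3a11 fell from 6030 to 3420 CPM. Genes of fatty acid synthesis and lipid storage went both ways (14 higher and 11 lower of 28, median 0.06, or 0.21 in FPKM values; mean -0.23, downward adjusted p = 0.0066, but adjusted p = 0.124 with an estimated correlation); the median turned to -0.04 with the GC trend removed. Thrsp, a lipogenic regulator, fell from 1410 ± 15 to 155 ± 5.6 CPM. Not called were pericentral hepatocyte genes (8 higher and 8 lower of 20, median 0.02, adjusted p = 0.76), bile acid genes (10 higher and 10 lower of 20, median 0.02, adjusted p = 0.81), gluconeogenesis and glycogen genes (5 higher and 11 lower of 18, median -0.18, mean 0.13, adjusted p = 0.52) and genes higher in female liver (1 higher and 5 lower of 8, median -0.71, adjusted p = 0.63).

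With EGCG, drug-metabolising enzymes, genes higher in male liver and PPAR-alpha targets, which had fallen, moved the other way. Drug-metabolising enzymes rose in 22 and fell in 5 of 30 (median 0.37, adjusted p = 5.2e-09), genes higher in male liver rose in 12 and fell in 1 of 15 (median 0.58, adjusted p = 4.5e-12), and genes of fatty acid synthesis, which had gone both ways with age, rose in 21 and fell in 6 of 28 (median 0.45, adjusted p = 3.1e-07). Thrsp rose to 480 ± 17 CPM, Me1, malic enzyme, from 114 to 281 CPM and Elovl3 from 191 to 622 CPM, whereas Lpin1 fell from 391 ± 8.7 to 54 ± 2.1 CPM. PPAR-alpha targets rose in 18 and fell in 6 of 30 (19 higher adjusted over the list alone; median 0.24, or 0.11 with the length trend removed; adjusted p = 0.0059), with Cyp4a14 at 235 ± 1.4 CPM and Angptl4 down from 139 to 27.4 CPM. Periportal genes fell in 10 and rose in 7 of 20 (median -0.09, or -0.23 with the length trend removed and -0.03 with upper-quartile factors; adjusted p = 0.045, but adjusted p = 0.179 with an estimated correlation), and genes of the urea cycle and amino acid breakdown were not called (14 higher and 6 lower of 25, median 0.12, adjusted p = 0.13). Pericentral genes rose in 12 and fell in 5 of 20 (median 0.16) and genes higher in female liver rose in 5 and fell in 1 of 8 (median 1.24, or 0.39 in FPKM values), both at adjusted p = 0.042, but adjusted p = 0.149 with an estimated correlation. Gluconeogenesis and glycogen genes fell in 12 and rose in 5 of 18 (median -0.34, adjusted p = 6.6e-05). Pck1, the entry enzyme of gluconeogenesis, fell from 3680 ± 45 to 1540 ± 8.6 CPM. Bile acid genes did not pass as a list (12 higher and 6 lower of 20, median 0.12, adjusted p = 0.054), but Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 102 ± 6.5 to 24.6 ± 0.39 CPM while Nr0b2, whose product represses it, rose by 2.76. Against the young libraries, the treated ones had lower periportal genes (15 lower and 3 higher of 20, median -0.56, adjusted p = 1e-09) and lower gluconeogenesis genes (12 lower and 4 higher of 18, median -0.45, or -0.29 with upper-quartile factors; adjusted p = 0.00047). PPAR-alpha targets were also still lower than in young libraries (20 lower and 8 higher of 30, median -0.36, or -0.14 in FPKM values; adjusted p = 0.0018), as were genes of the urea cycle and amino acid breakdown (18 lower and 4 higher of 25, median -0.32, or -0.14 in FPKM values; adjusted p = 1.8e-07, but adjusted p = 0.0861 with an estimated correlation). Drug-metabolising enzymes (17 higher and 12 lower of 30, or 17 and 13 adjusted over the list alone; adjusted p = 0.89) and genes higher in male liver (5 higher and 9 lower of 15, median -0.36, adjusted p = 0.76) were not called there.

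The libraries labelled retina were rich in transcripts of the liver, and a candidate explanation is that they came from liver in place of retina. The 24 genes of the plasma protein list, of which Trf, Ttr and Rbp4 are also known to be active in the eye, took at least 20.5% of the counts in every library, with Alb alone at 7.77 to 9.09% by group. Liver RNA mixed into retinal RNA is argued against by the rod photoreceptor genes, whose highest library median was 0.621 CPM. For a table whose gene names were shifted against its values, 23 plasma protein genes were found among the 100 genes with the highest counts. Chance gives 0.148 only for a list chosen without regard to abundance. This list was written after the most abundant transcripts had been seen, so its overlap is no independent test of such a shift. Whether a label, the dissection or the choice of deposited table lies behind this stays open, and no biological explanation was tested because the design names no other tissue.

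Clock genes moved in opposite directions between treated and untreated aged libraries: the median change was 1.89 (95% bootstrap interval over genes -0.24 to 3.29) for Arntl, Npas2, Clock, Cry1 and Nfil3, and -2.18 (-4.03 to -0.87) for 10 genes that include Dbp, Per1 and Nr1d1. The difference of 4.07 (1.6 to 6.14) is of the kind that collection of the groups at different times of day may give. The trend of fold changes with gene length is argued against, since the difference was 4.15 (1.78 to 6.27) with that trend removed. Between aged and young libraries the difference was 0.69 (-1.03 to 3.69), and between treated aged and young libraries 3.54 (1.49 to 9.19). The former does not show that aged and young libraries matched, because 9 of 19 clock genes rose and 7 fell with age. Arntl and Nr1d1, which stand on different sides of this contrast, both rose with age. The labels give no time of collection, and an action of the treatment on the clock stays open, untested.

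Cyfip2 rose with age and fell with EGCG, as did markers of liver macrophages (24 genes, 9 of them also in the microglia and macrophage list), sinusoidal endothelium (20 genes, 1 also in the endothelial list) and stellate cells (24 genes, 23 tested, 4 also in the fibroblast list and 2 in the matrix list), whose abundant members in aged libraries included Lyz2 (156 CPM), Cd5l (147), Bgn (133) and Reln (111). Whether the change of Cyfip2 follows these cells cannot be told apart from a change within cells. It lay at the 55.2 percentile of the 67 markers with age and at the 28.4 percentile with EGCG, which only restates that they moved together. With age, macrophage and endothelial medians of 2.21 and 1.05 differed by 1.16 (0.72 to 1.62 by bootstrap over genes, which are not independent). The 2 sets of markers thus did not rise by an equal amount. This does not decide on a common change in the share of all these cells, because expression of the markers in other cells was not tested. With EGCG the medians differed by 0.36 (-0.2 to 0.74), and such a common change stays open as well. The trend with gene length is argued against with EGCG, since the median of the markers was -1.25 (-1.39 to -1.09) with it removed and -1.12 before. A change of Cyfip2 within cells, from age or treatment, was not tested.

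Other groupings of the libraries were tried. For each pair of groups, 10 splits of 6 libraries exist, too few for a share under 0.05. The real split and the highest other gave 8857 and 0 genes for aged against young, 8064 and 0 for EGCG-treated aged against aged, and 8014 and 0 for EGCG-treated aged against young. For gene lists the values were 17 and 15, 18 and 18, and 14 and 8, so that 1, 2 and 1 of the splits gave as many lists as the real one. With EGCG the number of called lists therefore did not set the real grouping apart, and with age it did so by little. Every other split mixes both groups unevenly and keeps part of their difference, so its lists are no measure of chance. Mixing the groups also widens the spread within each side, so the 0 genes of the other splits were likely from the outset. For the 4678 opposite calls, 100 groupings of the 9 libraries were drawn, and the highest other value was 3463. This does not exclude chance in how the libraries were grouped. Libraries of a group lay close together, so groupings that mix them were likely to give fewer calls. The draw could also hold the real groups under other labels. Nor does the draw speak to differences between animals, since no label says that the libraries of a group came from separate ones.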
